A study of Arabidopsis thaliana with 12 samples.

How the data were processed

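RNA sequencing of whole Arabidopsis thaliana seedlings was performed on 12 libraries in 4 groups of 3. Per the labels, plants grew in soil under long days at about 21 °C after 4 days of stratification at 4 °C, and were harvested 12 days after germination. The sample titles place the libraries in 2 experiments. Experiment 1 holds wild-type Columbia-0 (Col-0) and hira-1, and experiment 2 holds a separate set of Col-0 and fas2-4. Each mutant was compared with the Col-0 libraries of its own experiment. HIRA encodes a histone chaperone of the H3.3 variant, and FAS2 encodes a subunit of chromatin assembly factor 1 (CAF-1), which deposits H3.1 at replicating DNA.

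Per the labels' protocols, total RNA was purified on columns and libraries were made and sequenced by a service provider. Reads were trimmed with fastp 0.23.4 and aligned to TAIR10 with HISAT2 2.2.1, per the submitters' processing notes. The counting program, the annotation version and the use of strand were not given in the sources used here. The authors deposited 1 table of read counts per gene and 1 table of TMM-scaled TPM values per experiment. The deposited TMM-scaled TPM values are a score per gene made from TPM (counts scaled by gene length and library size) and a library factor. They were checked against TPM recomputed from the deposited counts and lengths. In each library, 100% of the genes with at least 200 counts lay within 0.5% of the library's own ratio. All 24 value columns were used.

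The total count per library was 20700171 to 21902258 in experiment 1 and 39258873 to 39510509 in experiment 2. Organellar genes took 0.0796% to 0.458% of the counts. No pair of libraries within a group was a duplicate. The tables hold 32833 genes, of which 32548 matched the TAIR10.1 reference by identifier. The other 285 are organellar identifiers. Positions, exon lengths and GC content come from that reference, and 10082 genes (30.7%) overlap another counted gene. Because the use of strand is not known, values of overlapping genes are uncertain, and so are those of near-identical copies such as the histone H3, LHCB1, RBCS and PDF1.2 genes. Where a gene had no counts in a group, its fold change was bounded with a floor of 3 counts over the group. Such bounds cover counting error only.

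Counts were filtered with filterByExpr by group, scaled with TMM, and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest, 2-sided). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison, and each adjusted p of a gene below is of this kind. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. Expression levels are TMM-scaled CPM (counts scaled by library size), as mean ± SD over 3 libraries. The difference between the fas2-4 and hira-1 effects was tested as a contrast over all 12 libraries with 1 mean per group. Calls of the mutants were compared with 1-sided Fisher's exact tests over the genes tested in both comparisons. The Col-0 sets of the experiments were also compared with each other. Called genes were tested for clustering by chromosome, within 1 Mb (or 2 Mb) of a chromosome end, and within 1 Mb of the targeted gene, by Fisher's exact test.

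For gene groups, 27 lists of 375 genes were written before the data were examined, as were the designs, the rule for named genes and the other settings to be tried. The lists cover histone chaperones, H3.1 genes, H3.3 genes, DNA damage response, S phase, G2 and M phase, endoreduplication and CDK inhibitors, and DNA methylation and Polycomb machinery. They also cover flowering time, floral organ identity, shoot meristem, salicylic acid and immune defence, jasmonate and ethylene defence, and light harvesting and photosynthesis. Further lists are circadian clock, cold and water-deficit response, heat shock, anthocyanin and flavonoid synthesis, iron deficiency, phosphate starvation, senescence, and nucleolus and telomere. The last are root cell, stomatal lineage, and trichome and epidermis markers, silenced loci, and seed regulators and storage. Each list with at least 3 tested members was tested against the other genes with camera in limma 3.58.1 (preset correlation 0.01, voom values), with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Counts of called members are also given adjusted over the list alone.

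Named genes are HIRA, FAS2, FAS1 and the histone H3.1 and H3.3 genes, and the 10 largest rises and 10 largest falls per comparison (5 each for the difference). Those needed a mean of at least 5 CPM in a group and, except for the difference, no overlap of libraries. Up to 4 members with the smallest adjusted p were named from each list that passed camera or had 3 called members. From the genes called in both mutants, the 5 with the strongest evidence in each pair of directions were named.

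The other settings were a 2-fold minimum, RLE and upper-quartile scaling, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, and limma on log2 TMM-scaled TPM with a pseudocount of 1 or 0.1. Further ones were all 12 libraries in 1 fit, the replicate number as a block, and leaving out each library in turn. After the data were seen, corrections for exon length and GC content were added: a lowess curve per library (span 0.3, 3 iterations) was taken out through the offset. Libraries with the same replicate number were checked for shared deviations from their group means. In experiment 1 the correlations across genes were 0.281, 0.536 and 0.637, each above 0.1, so the numbers were taken to pair the libraries. In experiment 2 they were -0.0663, 0.163 and 0.00638, so the libraries share only a number. The pairing comes from these values and not from the labels.

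The tests were tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. The experiment 1 comparison (18739 genes) recovered 16 of the 2-fold and 94 of the 4-fold genes. The experiment 2 comparison (20004 genes) recovered 72 and 96, the difference (20152 genes) 3 and 70, and the Col-0 comparison (19365 genes) 74 and 97. With the length trend of experiment 1 added to that comparison's simulation, 103 unchanged genes were called without the length correction and 7 with it. The added trend was the same lowess curve that the correction takes out. The fall to 7 was therefore built in, and it does not test the correction on the real data. A planned test of transposable-element genes was not run, because the reference types only 1 of the counted genes as a pseudogene and marks no counted gene as a transposable-element gene. The labels name separate samples but not separate cultures, so p-values measure only the spread between these samples.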

Results

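The data are read counts for 32833 genes in whole seedlings 12 days after germination. The 3 libraries labelled hira-1 and their 3 Col-0 libraries (experiment 1) held 20700171 to 21902258 counts each. The 3 fas2-4 libraries and their 3 Col-0 libraries (experiment 2) held 39258873 to 39510509. The series title asks about CAF-1 and the incorporation of H3.3, and the comparisons show which transcripts differ in libraries labelled as mutants of HIRA and of the CAF-1 subunit FAS2. Every group has n = 3.

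HIRA (AT3G44530, chromosome 3, 16115498 to 16121534, TAIR10.1) was not lower in the libraries labelled hira-1. Its counts were 223, 300 and 203 in Col-0 and 235, 286 and 454 in the libraries labelled hira-1. The means were 10.9 ± 2.2 and 16.04 ± 6.6 CPM, a log2 fold change of +0.56 (SE 0.30, edgeR adjusted p = 0.198). With the length correction the log2 fold change was +1.49 and passed the threshold (adjusted p = 0.0489). The level of HIRA therefore does not bear out the label. It cannot decide against the label either, because transcripts of the disrupted gene could still be counted, which values per gene do not show. FAS2 (AT5G64630, chromosome 5, 25833165 to 25836400) had 273, 286 and 253 counts in Col-0 and 197, 207 and 281 in fas2-4. Its means were 7.24 ± 0.39 and 5.49 ± 0.88 CPM, a log2 fold change of -0.40 (SE 0.16, adjusted p = 0.156), so FAS2 was not called. In CPM all 3 fas2-4 libraries lay below all 3 Col-0 libraries. In that comparison 31.7% of tested genes showed such a separation, in either direction. FAS2 in the libraries labelled hira-1 had a log2 fold change of -0.65 (SE 0.31, adjusted p = 0.162), and with the replicate block it was called (-0.63, adjusted p = 0.0381). HIRA in fas2-4 had a log2 fold change of -0.14 (SE 0.16, adjusted p = 0.663). FAS1, which encodes another CAF-1 subunit, had +0.04 in fas2-4 (adjusted p = 0.957). In the libraries labelled hira-1, FAS1 had -1.17 (SE 0.39, adjusted p = 0.0677), and it was called with the block (-1.21, adjusted p = 0.00017). The block did not take out the dependence of fold changes on exon length in these libraries, which is described below. The calls of FAS2 and FAS1 with the block alone therefore do not separate a lower level from that trend.

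**Figure D1:**
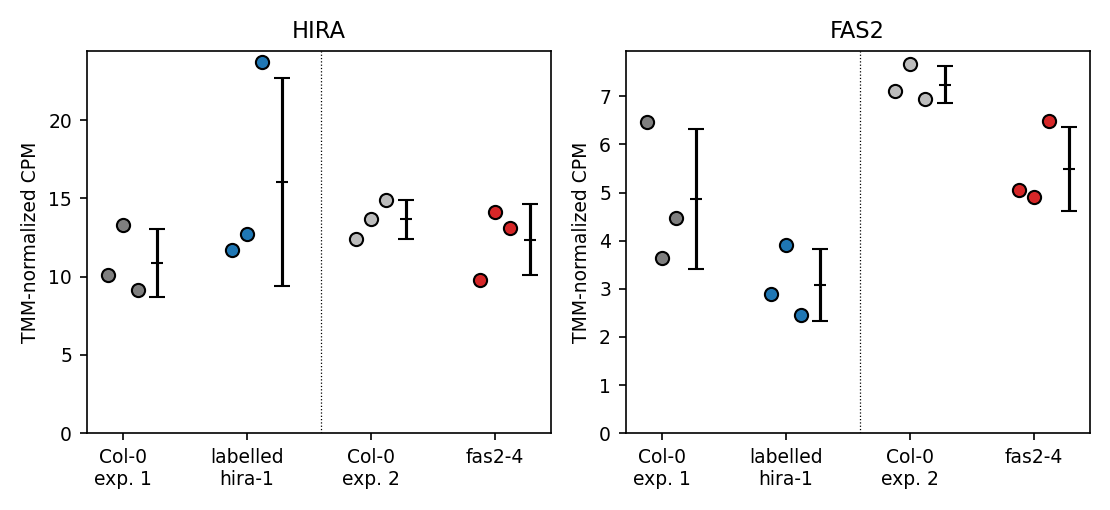
Expression of HIRA and FAS2 in CPM in each of the 12 libraries, by group; points are libraries. HIRA lies between 9.17 and 13.3 CPM in Col-0 of experiment 1 and between 11.7 and 23.7 CPM in the libraries labelled hira-1.

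In fas2-4, genes of the DNA damage response rose strongly. SMR7, which encodes a CDK inhibitor, rose from 0.491 ± 0.11 to 26.5 ± 8.4 CPM, a log2 fold change of +5.74 (SE 0.30, adjusted p = 5.94e-05). The transcription factor gene ANAC044 rose by 4.95 (SE 0.20, adjusted p = 1.25e-05) and XRI1 by 2.81 (SE 0.19, adjusted p = 0.000185) on the same scale. Of 26 tested genes of this list, 16 rose, 0 fell and 10 were not called. The count was 18 up adjusted over the list alone, with a median of +1.38 (camera adjusted p = 1.47e-13, adjusted p = 0.254 with an estimated correlation). SMR7, ANAC044 and XRI1 each kept the call when any of the 6 libraries was left out.

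Many cell division genes of G2 and M phase rose in fas2-4 too, with a smaller median change than the DNA damage list. CDKB1;1 rose by 1.23 on the log2 scale (SE 0.14, adjusted p = 0.00204), CDKB2;1 by 0.95 (SE 0.11, adjusted p = 0.00229), CDKB1;2 by 1.16 and CYCB1;3 by 1.12. Of 23 tested genes, 15 rose and 0 fell (20 up adjusted over the list alone, median +0.77, camera adjusted p = 2.67e-12, adjusted p = 0.254 with an estimated correlation). The S phase list did not pass, with 0 up and 1 down of 22 (camera adjusted p = 0.485), but it did without fas2-4 replicate 3 (adjusted p = 0.044), and adjusted over the list alone it had 0 calls. Endoreduplication genes gave 1 up and 1 down of 9 (2 up and 1 down adjusted over the list alone, camera adjusted p = 0.485).

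Histone H3 genes differed in fas2-4. Of the 5 H3.1 genes, HTR3 (+1.14, SE 0.14, adjusted p = 0.00283), HTR2 (+0.77), HTR9 (+0.62) and HTR1 (+0.51) rose, and HTR13 was not called (+0.31, adjusted p = 0.2). Adjusted over the list alone the count was also 4 up (median +0.62, camera adjusted p = 0.000147, adjusted p = 0.254 with an estimated correlation). Of the 3 H3.3 genes, HTR8 rose (+0.62, SE 0.13, adjusted p = 0.02), HTR4 (-0.28, adjusted p = 0.274) and HTR5 (+0.12, adjusted p = 0.751) were not called, and the list did not pass (1 up and 0 down adjusted over the list alone, camera adjusted p = 0.675). A pair of further genes annotated as histone superfamily proteins rose steeply. AT1G75600 had no counts in Col-0 and 6.12 ± 0.30 CPM in fas2-4, at least 229-fold higher, and AT1G13370 rose from 0.874 ± 0.11 to 14.2 ± 2.9 CPM (log2 +4.02, SE 0.21, adjusted p = 5.94e-05). The 20 histone chaperone genes gave 0 calls by edgeR, 2 at an unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 0.579). The calls of HTR1, HTR2, HTR9 and HTR8 were each lost in 2 to 4 of the 6 fits without a library, and H3 copies share sequence, so single H3 genes are uncertain.

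Defence and pigment genes also rose in fas2-4. PR2, which encodes a glucanase, rose by 2.21 on the log2 scale (SE 0.23, adjusted p = 0.00124), and ICS1, which encodes an enzyme of salicylic acid synthesis, by 1.25 (SE 0.14, adjusted p = 0.00203). WRKY46 rose by 1.54 and SARD1 by 1.43. Of 29 salicylic acid and immune genes, 19 rose and 0 fell (26 up adjusted over the list alone, median +1.25, camera adjusted p = 1.81e-14, adjusted p = 0.254 with an estimated correlation). None of 17 jasmonate and ethylene genes was called by edgeR, against 4 at an unadjusted p under 0.05 and 2 by DESeq2 (camera adjusted p = 0.494). That list passed without fas2-4 replicate 3 (adjusted p = 0.00347). Among anthocyanin genes, LDOX rose by 2.14 (SE 0.27, adjusted p = 0.00276), UF3GT by 2.21, DFR by 2.02 and the regulator PAP1 by 1.46. In that list 7 of 13 rose and 0 fell (10 up and 1 down adjusted over the list alone, median +1.31, camera adjusted p = 5.24e-06, adjusted p = 0.403 with an estimated correlation). The PAP1 call was lost in 2 of the 6 fits without a library. Members of this list also differed between the Col-0 sets, where 9 of 14 were called, against 33.6% of all tested genes. With all 12 libraries scaled together, DFR had 53.9 CPM in fas2-4 but 73.8 in Col-0 of experiment 1. The means of UF3GT, TT8 and F3'H were higher in fas2-4 than in either Col-0 set, but with a wide spread. In fas2-4 and in Col-0 of experiment 1, UF3GT had 14.2 ± 5.9 and 10.4 ± 3.2 CPM. TT8 had 2.42 ± 1.5 and 1.86 ± 0.72, and F3'H 21.6 ± 9.1 and 12.6 ± 3.2. These 2 groups were not tested against each other.

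Flowering and meristem genes shifted in fas2-4 as well. The floral repressor FLC fell by 3.13 on the log2 scale (SE 0.35, adjusted p = 0.00186) and MAF4 by 1.68 (SE 0.24, adjusted p = 0.0048), while the floral promoter FT rose by 2.17 (SE 0.22, adjusted p = 0.00115) and AGL19 by 2.01. Of 14 flowering time genes, 5 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.775). Between the Col-0 sets 7 of 14 flowering time genes were called, against 33.6% of all tested genes. FT was 1 of them and was lower in Col-0 of experiment 2, so its rise in fas2-4 starts from the lower wild-type level. Levels in fas2-4 were not tested against Col-0 of experiment 1. The floral organ genes SEP3 (+3.45, SE 0.33, adjusted p = 0.000945), SEP2 (+4.54), AP1 (+3.34) and LFY (+2.201) rose from low levels of 0.0621 to 0.526 CPM. Of 10 floral organ identity genes, 7 rose and 0 fell (9 up and 1 down adjusted over the list alone, median +2.52, camera adjusted p = 2.01e-06, adjusted p = 0.254 with an estimated correlation). The homeobox genes STM (+1.18, SE 0.17, adjusted p = 0.00469), KNAT1 (+1.09), KNAT6 (+1.001) and KNAT2 (+0.84) made 4 of 5 shoot meristem genes that rose, with 0 down (4 up and 1 down adjusted over the list alone, median +1.001, camera adjusted p = 0.00767, adjusted p = 0.254 with an estimated correlation). KNAT2 was called in only 1 of the 6 fits without a library.

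A few photosynthesis and stomatal genes were called by edgeR in fas2-4, each of them lower. RBCS3B fell by 0.61 on the log2 scale (SE 0.14, adjusted p = 0.0254), RBCS1A by 0.58 (SE 0.14, adjusted p = 0.0344) and LHCB1.1 by 0.67 (SE 0.16, adjusted p = 0.0359). These were 3 of 30 genes of the list, with 0 up (0 up and 7 down adjusted over the list alone, median -0.40, camera adjusted p = 2.89e-09, adjusted p = 0.337 with an estimated correlation). Each of the 3 calls was lost in 4 or 5 of the 6 fits without a library. The count depends on the method: 19 photosynthesis genes had an unadjusted p under 0.05, and DESeq2 called 14. The stomatal lineage gene MUTE fell by 1.01 (SE 0.17, adjusted p = 0.00904), the only call among 7 (0 up and 3 down adjusted over the list alone, median -0.39, camera adjusted p = 0.0014, adjusted p = 0.254 with an estimated correlation).

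The other lists did not pass camera in fas2-4. Counts up and down were 2 and 2 of 16 for cold and water deficit, 3 and 0 of 11 for senescence, 1 and 0 of 7 for heat shock and 0 and 1 of 7 for phosphate starvation. They were 1 and 0 of 8 for nucleolus and telomere, 1 and 0 of 5 for root cell markers, and 0 and 1 of 7 for trichome and epidermis. Adjusted over the list alone, the counts became 2 and 3 for cold and water deficit, 4 and 0 for senescence, 0 and 2 for phosphate starvation, 1 and 1 for root cell markers and 0 and 1 for iron deficiency. Over all genes, no gene was called by edgeR among 17 of DNA methylation and Polycomb, 16 of the circadian clock and 7 of iron deficiency. At an unadjusted p under 0.05 these lists had 3, 2 and 2 genes, and DESeq2 called 1 in each. Their camera adjusted p values lay between 0.0943 (senescence) and 0.775. Senescence passed without Col-0 replicate 2 (adjusted p = 0.0278), iron deficiency without Col-0 replicate 3 (0.0404) or fas2-4 replicate 1 (0.0268), and DNA methylation and Polycomb without the latter (0.023). The called genes included RD26 (+1.34), RD20 (+0.94), KIN2 (-0.99), RAB18 (-0.998), SAG13 (+2.08), WRKY75 (+2.17) and SGR1 (+0.49), each of which lost its call without some library. Silenced loci had 1 tested gene, which fell (-1.07), and seed regulators and storage had 1, which was not called.

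Among single genes in fas2-4 with at least 5 CPM in a group, AT1G75945 (log2 +8.04, SE 0.46, adjusted p = 7.4e-05), AT4G22960 (+6.46, SE 0.21, adjusted p = 3.08e-06) and AT2G18193 (+6.13, SE 0.17, adjusted p = 1.61e-06) stood at the top with AT1G75600 and SMR7. AT5G60250 (+5.01), AT1G68200 (+4.27) and GMI1 (+4.19) followed. At the same level, the 10 deepest falls were AT2G01422 (-4.44, SE 0.23, adjusted p = 5.94e-05), AT2G05995 (-4.06), AT4G19430 (-2.90), AT5G35480 (-2.62), MRU1 (-2.41), AT4G27570 (-1.89), AT3G55646 (-1.81), AT1G74290 (-1.81), AT5G54585 (-1.81) and AT3G16670 (-1.78). AT2G01422 and AT2G05995 are annotated as non-coding RNA. AT2G01422 also differed between the Col-0 sets. It was higher in Col-0 of experiment 2 than of experiment 1, by more than it fell in fas2-4. In all, 1948 of 20004 genes were called by edgeR, 1356 up and 592 down, of which 993 (831 up, 162 down) differed at least 2-fold. The libraries of the groups did not overlap for 6343 genes (31.7%), where chance gives 10%. Leaving out Col-0 replicate 1, 2 or 3 gave 679, 725 or 643 calls, and leaving out fas2-4 replicate 1, 2 or 3 gave 5661, 1453 or 1039. The length correction gave 3333 calls. Of 78 called genes picked by the rule for names, 51 were called in each of these 6 fits. The share of rises among the calls was 69.6%, but 58.7% with DESeq2 and 57.8% with the length correction.

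**Figure D2:**
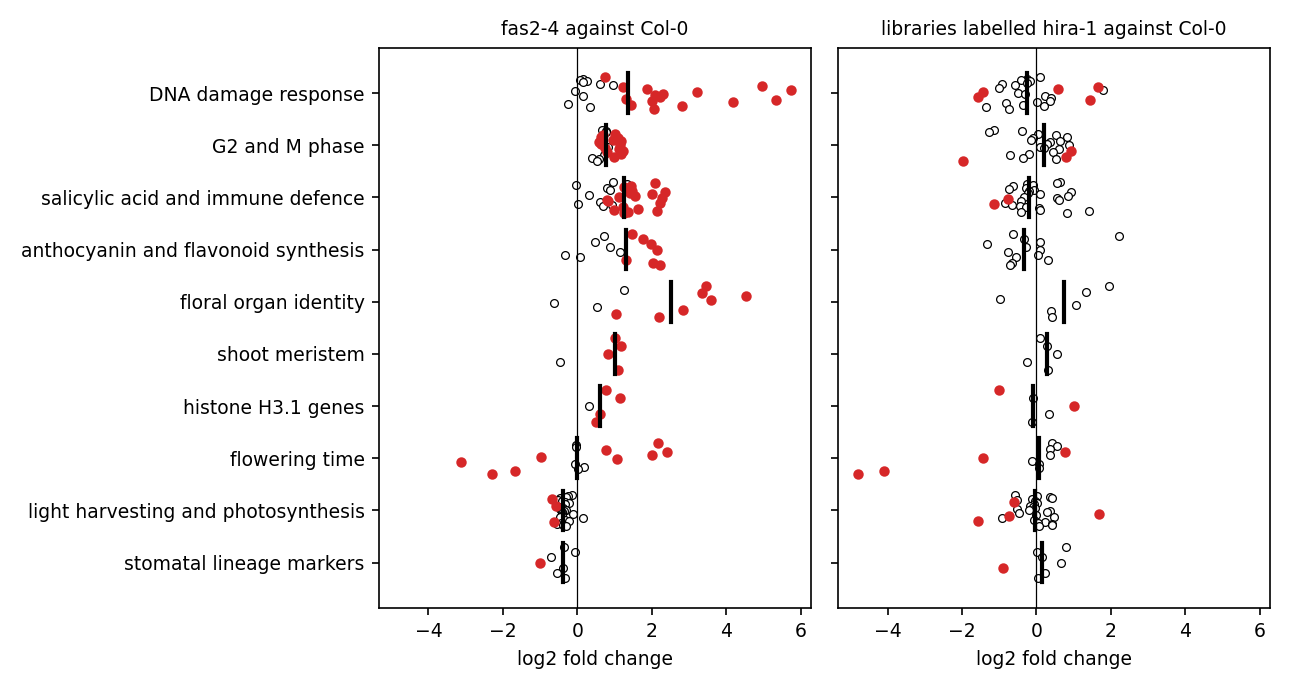
Log2 fold changes of the tested genes of some of the fixed lists in fas2-4 and in the libraries labelled hira-1, each against its own Col-0. Filled points are genes called by edgeR, open points are genes not called, and bars are list medians. Camera results are not drawn. In fas2-4, 9 of 25 tested lists passed camera, and in the libraries labelled hira-1 0 of 25 passed.

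In the libraries labelled hira-1, a small set of genes went from almost no counts to clear expression. The direction here is that of the labels, which the HIRA level does not bear out. AT3G29639 rose from 0.898 ± 0.037 to 258 ± 36 CPM (log2 +8.16, SE 0.24, adjusted p = 7.46e-07). AT1G75945 rose by 8.02 (SE 0.51, adjusted p = 0.000251), AT1G36675 by 7.38 (SE 0.34, adjusted p = 2.73e-05) and AT1G06993 by 7.27 (SE 0.53, adjusted p = 0.000674) on the log2 scale. AT1G64795 had no counts in Col-0 and 9.67 ± 3.2 CPM in the libraries labelled hira-1, at least 215-fold higher. It overlaps a gene on the opposite strand. AT3G29633 (+5.86), AT4G07995 (+5.35, SE 0.34, adjusted p = 0.000251), AT5G35480 (+4.33, SE 0.36, adjusted p = 0.00139), MRU1 (+3.52, SE 0.26, adjusted p = 0.000725) and AT1G65240 (+3.48) complete the 10 largest rises among genes with at least 5 CPM in a group and no overlap of libraries. The 10 deepest falls among such genes were AT3G05955 (-3.88), AT2G01021 (-3.14, not called with the block, adjusted p = 0.0839), HO3, a heme oxygenase gene (-2.93, SE 0.31, adjusted p = 0.00488), HAF01 (-2.75), RTL2 (-2.74), NET1B (-2.60), CFM3B (-2.47), TOPII (-2.37), CFM3A (-2.35) and AT1G64330 (-2.34). With the length correction HAF01 was at -1.66, NET1B at -1.53 and TOPII at -1.44, all still called. Of 62 named called genes in this comparison, 11 kept their call without any 1 of the 6 libraries. These are AT1G64795, AT3G29639, AT1G75945, AT1G36675, AT1G06993, AT4G07995, AT5G35480, MRU1, HO3, AT5G52070 (+2.38) and AT3G28540 (-2.20), and the other 51 were lost without some library.

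Of the 13 genes at least 16-fold higher in the libraries labelled hira-1, 11 lay in the 10% of tested genes with most annotated pseudogenes within 500 kb, against 2 of 25 in fas2-4. This comparison was chosen after the positions were seen.

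**Figure D3:**
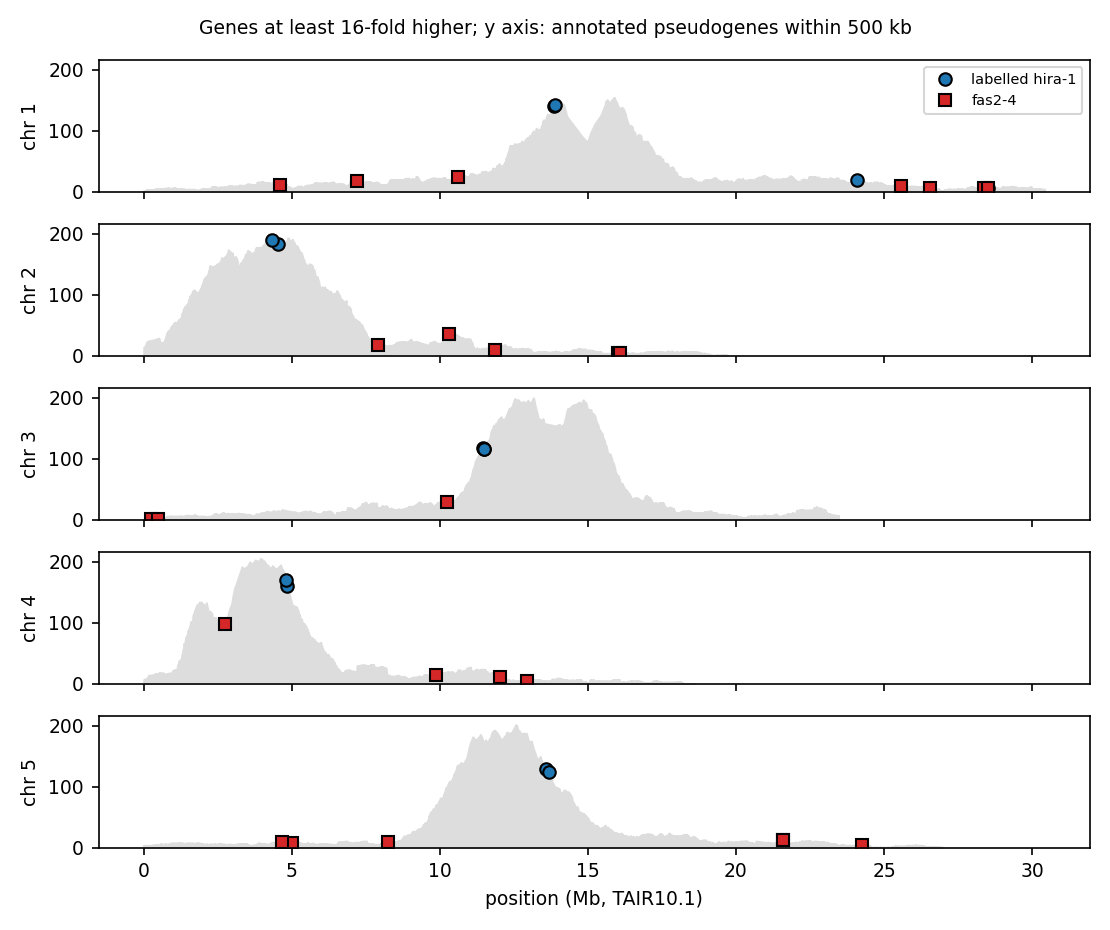
Positions of genes at least 16-fold higher in the libraries labelled hira-1 (circles) and in fas2-4 (squares) along the 5 chromosomes in Mb; height is the number of annotated pseudogenes within 500 kb, with that of each tested gene as a grey background. Of the 13 genes of the libraries labelled hira-1, 11 have at least 30 such pseudogenes.

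Histone, flowering and stress genes were called singly in the libraries labelled hira-1. HTR13 rose (+1.01, SE 0.19, adjusted p = 0.023) and HTR2 fell (-0.999, SE 0.20, adjusted p = 0.0248) among the 5 H3.1 genes, with the same counts adjusted over the list alone. These are short genes, and with the length correction HTR13 was not called (+0.48, adjusted p = 0.0547), while HTR2 (-1.49) and HTR1 (-0.64, adjusted p = 0.0231) were. HTR13 was called with length correction and block together (adjusted p = 0.00174). Without a correction HTR1 (-0.12), HTR3 (-0.09) and HTR9 (+0.34, adjusted p = 0.18) were not called, although HTR9 was with the block (adjusted p = 0.017). None of the 3 H3.3 genes was called over all genes by edgeR, while all 3 had an unadjusted p under 0.05 and DESeq2 called 2. HTR4 (+0.59), HTR5 (-0.62) and HTR8 (-0.50) had adjusted p values of 0.058, 0.0682 and 0.0858. With the block they were 5.42e-05, 1.84e-05 and 0.00036, and adjusted over the list alone 1 rose and 2 fell. The length correction called HTR5 (-0.76, adjusted p = 0.0272) and HTR8 (-0.97, adjusted p = 0.00661). The flowering genes MAF5 (-4.80, SE 0.57, adjusted p = 0.00828), MAF4 (-4.10, SE 0.73, adjusted p = 0.0222) and AGL24 (-1.42, SE 0.21, adjusted p = 0.0177) fell and SOC1 rose (+0.76), a count of 1 up and 3 down of 11 flowering time genes. HSP70 (-1.89), HSP101 (-1.51), HSP90.1 (-1.04) and MBF1C (-0.94) fell among 6 heat shock genes, and COR47 (-1.27), ERD10 (-1.18) and RAB18 (-1.58) among 13 of cold and water deficit. Among 20 histone chaperone genes, ASF1A (+0.84) and ASF1B (+0.90) rose, and SPT6L (-1.85) and NAP1;1 (-0.79) fell. ANAC044 (+1.66), SMR4 (+1.45) and TSO2 (+0.58) rose and TEB fell (-1.58) in the DNA damage list, which had 3 up and 2 down of 25. In the G2 and M phase list, CDKB1;1 (+0.93) and CYCB2;2 (+0.79) rose and PLE fell (-1.96), 2 up and 1 down of 23, and CYCA1;1 was not called (+0.83, adjusted p = 0.0517). It was with the block, by DESeq2, with the length correction and adjusted over the list alone. GUN4 rose (+1.67) and CHLH (-1.57), PSAD1 (-0.75) and GAPB (-0.60) fell, 1 up and 3 down of 30 photosynthesis genes. None of these single calls was kept in each fit without a library. The length correction also ended the calls of ASF1A (+0.52), HSP101 (-0.90), HSP90.1 (-0.90), SMR4 (+0.90) and TEB (-0.37), and moved SPT6L to -0.78 and CHLH to -0.70. With length correction and block together, TEB alone of these 5 was not called.

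No list passed camera in the libraries labelled hira-1, and the lowest adjusted p values were 0.226 for heat shock and for DNA methylation and Polycomb (0.89 with an estimated correlation). At an unadjusted p under 0.05, 4 lists passed camera and 4 passed fry, and 0 passed fry after adjustment. Counts up and down were 1 and 1 of 22 for S phase, 2 and 0 of 9 for endoreduplication, 0 and 2 of 17 for DNA methylation and Polycomb, and 0 and 2 of 28 for salicylic acid. They were 1 and 0 of 17 for jasmonate and ethylene, 0 and 1 of 13 for the circadian clock, 1 and 0 of 5 for phosphate starvation, 1 and 0 of 11 for senescence, and 0 and 1 of 7 for stomatal lineage. Adjusted over the list alone, the counts became 2 and 2 for S phase, 0 and 0 for salicylic acid, 0 and 4 for the clock, 3 and 0 for phosphate starvation and 1 and 1 for senescence. They also became 4 and 3 for DNA damage, 3 and 1 for G2 and M phase, 2 and 3 for flowering time and 0 and 4 for cold and water deficit. The floral organ, shoot meristem, anthocyanin, iron, nucleolus, root and trichome lists had 0 calls by edgeR among 6, 5, 13, 4, 6, 3 and 7 genes. At an unadjusted p under 0.05 they had 4, 0, 5, 0, 2, 0 and 1 genes, and DESeq2 called 3, 0, 2, 0, 1, 0 and 0. Adjusted over the list alone, the floral organ list had 3 up and 1 down and the other 6 had 0 calls. With the replicate block edgeR called 3 up and 1 down, 0, 2 up and 6 down, 1 up, 1 up and 1 down, 1 down, and 1 up and 2 down in these lists. The 1 tested silenced locus was not called (adjusted p = 0.0978) except with the block and adjusted over the list alone, and no seed gene was tested. Counts up and down with the block were 2 and 10 for histone chaperones, 0 and 9 for DNA methylation and Polycomb, 0 and 7 for the circadian clock and for cold and water deficit, and 9 and 8 for photosynthesis. They were 4 and 6 for DNA damage, 5 and 7 for S phase, 7 and 4 for G2 and M phase, 3 and 4 for salicylic acid, 6 and 6 for jasmonate and ethylene, and 3 and 3 for flowering time. Endoreduplication gave 2 and 1, phosphate starvation 2 and 0, senescence 2 and 3, stomatal lineage 2 and 1, H3.1 genes 2 and 1 and heat shock 0 and 4. No list passed camera with the block. The block did not take out the dependence on exon length. With it, 124 genes were called higher and 2399 lower among the longest of 5 equal groups of genes by length. Among the shortest these counts were 1831 and 250. With the length correction, the cold and water-deficit list (adjusted p = 0.041) and the heat shock list (adjusted p = 0.049) passed, both lower (adjusted p = 0.959 for each with an estimated correlation). Without Col-0 replicate 3 the DNA methylation and Polycomb list passed (adjusted p = 0.0272), as it did without replicate 2 of the libraries labelled hira-1 (adjusted p = 0.0496).

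The fold changes of the libraries labelled hira-1 followed exon length. Their Spearman correlation with exon length across genes was -0.562, against -0.0536 in fas2-4 (genes are not independent replicates). The latter value averages unlike libraries: fas2-4 replicate 1 followed length (-0.448), and replicates 2 and 3 went the other way (+0.193 and +0.194). Among the shortest of 5 equal groups of genes by length, 697 were called higher and 77 lower, and among the longest 28 and 588. With the length correction these counts were 241 and 265, and 127 and 115. In all, 2575 of 18739 genes were called by edgeR, 1300 up and 1275 down, of which 1388 (620 up, 768 down) differed at least 2-fold. The libraries did not overlap for 7242 genes (38.6%), where chance gives 10%. The length correction gave 1887 calls, of which 1357 were among the 2575, and the replicate block gave 9593 (4485 up, 5108 down). Leaving out Col-0 replicate 1, 2 or 3 gave 19, 50 or 3553 calls, and leaving out replicate 1, 2 or 3 of the libraries labelled hira-1 gave 29, 5021 or 443. The share of rises was 50.5%, and 63.3% by limma on TMM-scaled TPM without a filter.

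**Figure D4:**
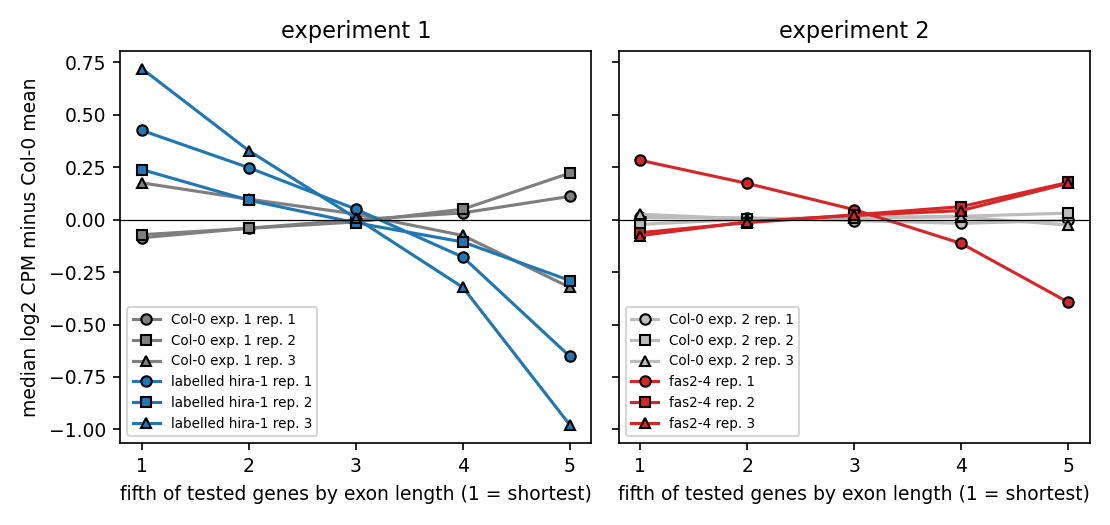
Median log2 deviation from the Col-0 mean (y axis) for 5 equal groups of genes by exon length (x axis) for each of the 12 libraries. In the longest group the libraries labelled hira-1 lie at -0.65, -0.29 and -0.98, and Col-0 replicate 3 of experiment 1 lies at -0.32.

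The test of the difference between the effects asks for which genes the 2 comparisons with Col-0 gave unlike effects. Positive values mean a higher effect in fas2-4. Each mutant is in 1 experiment only, so a difference between the mutants cannot be told apart from one between the experiments. The direction for hira-1 again rests on the labels. Of the lists, DNA damage response had the lowest adjusted p by camera with the preset correlation. Among DNA damage genes, SMR7 was at 3.94, PARP2 at 3.66, ANAC044 at 3.26 and XRI1 at 2.58 on the log2 scale. Of 26 such genes 15 were higher and 0 lower (17 up adjusted over the list alone, median +1.69, camera adjusted p = 4.44e-09, adjusted p = 0.495 with an estimated correlation). Salicylic acid genes gave 9 higher and 0 lower of 29 (11 up adjusted over the list alone, median +1.48, camera adjusted p = 4.12e-06, adjusted p = 0.495 with an estimated correlation), led by PR2 (3.06), SARD1 (2.06), EDS1 (1.54) and ICS1 (1.51). Anthocyanin genes gave 7 higher and 0 lower of 13 (8 up adjusted over the list alone, median +1.89, camera adjusted p = 0.00122, adjusted p = 0.526 with an estimated correlation), led by TT8 (3.28), UF3GT (2.92), DFR (2.67) and F3'H (1.89). The G2 and M phase list gave 3 higher and 0 lower of 23 (7 up adjusted over the list alone, median +0.53, camera adjusted p = 0.00122, adjusted p = 0.495 with an estimated correlation), with PLE at 2.46, CDKB2;1 at 1.06 and CYCB2;3 at 0.95. Photosynthesis genes gave 0 higher and 5 lower of 30 (0 up and 8 down adjusted over the list alone, median -0.38, camera adjusted p = 0.00236, adjusted p = 0.549 with an estimated correlation). RBCS1B was at -0.98, LHCB5 at -0.94, LHCB1.2 at -0.89 and RBCS3B at -0.87. The length correction ended the call of LHCB1.2 (-0.64, edgeR adjusted p = 0.0943). With the block the counts were 9 and 0 for G2 and M phase, 14 and 0 for salicylic acid and 2 and 11 for photosynthesis. HTR2 (1.76), HTR3 (1.22) and HTR1 (0.62) were higher among the H3.1 genes. HTR13 was at -0.72 (adjusted p = 0.053) and was called lower with the block (adjusted p = 0.0106), by DESeq2 (adjusted p = 0.0153) and adjusted over the list alone, but not with the length correction (-0.30, adjusted p = 0.209), alone or with the block (adjusted p = 0.129). The H3.1 list (adjusted p = 0.00136) and the heat shock list (adjusted p = 0.0376) passed camera only with the length correction or without some library (adjusted p = 0.425 and 0.466 with length correction and an estimated correlation). Of the 12 fits without a library, the H3.1 list passed in 3, heat shock in 5, phosphate starvation in 3 and DNA methylation and Polycomb in 4. In the same fits RBCS1B was called in 5, LHCB5 in 4, LHCB1.2 in 5, RBCS3B in 7, CDKB2;1 in 3, CYCB2;3 in 4, HTR1 in 3, TT8 in 10 and F3'H in 11.

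Among genes with at least 5 CPM in a group, the largest single differences toward fas2-4 were AT2G18193 (5.20, SE 0.48), AT1G68200 (5.06, SE 0.54), AT4G22960 (4.51, SE 0.68), SBT3.3 (4.13, SE 0.75) and GMI1 (4.12, SE 0.71). Toward the libraries labelled hira-1 they were AT3G29639 (-7.73, SE 0.40), AT1G36675 (-6.98, SE 0.61), AT5G35480 (-6.94, SE 0.45), AT1G06993 (-6.91, SE 1.74) and MRU1 (-5.93, SE 0.29). AT1G06993 was lost in 2 of the 12 fits without a library, and the other 9 were kept in each. SPX1 (-2.57), PAP17 (-1.77) and PHT1;4 (-1.35) of the phosphate starvation list were also lower, each called in 3 to 7 of the 12 fits. Their starting levels differed between the experiments. In Col-0 of experiments 1 and 2, SPX1 had 6.43 and 57.3 CPM, PAP17 11.9 and 146, and PHT1;4 1.74 and 11.1. In all, 2331 of 20152 genes were called by edgeR, 1176 higher and 1155 lower in fas2-4, and 6461 with the replicate block. The differences followed exon length across genes (Spearman correlation 0.438, genes are not independent replicates). The length correction gave 2884 calls, of which 1910 were among the 2331. Leaving out Col-0 replicate 1, 2 or 3 of experiment 1 gave 723, 1099 or 3751 calls, and leaving out replicate 2 or 3 of the libraries labelled hira-1 gave 4844 or 1303. Leaving out Col-0 replicate 1, 2 or 3 of experiment 2 gave 760, 975 or 835, and leaving out fas2-4 replicate 1, 2 or 3 gave 4449, 800 or 747.

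Genes called in both mutants were few. Of 18631 genes tested in both, 112 were higher in both against 76.9 expected of independent lists (odds ratio 1.55, 95% interval 1.26 to 1.91, Fisher's exact adjusted p = 0.00013). Lower in both were 39 against 38.7 (odds ratio 1.01), but without a filter this odds ratio passed (1.40, adjusted p = 0.0381). With the length correction 105 were lower in both against 69.8 (odds ratio 1.61, adjusted p = 2.89e-05). With length correction and block there were 334 against 252.7 (odds ratio 1.47, adjusted p = 2.99e-08), and the excess of genes higher in both was lost (odds ratio 1.02, adjusted p = 0.754). Higher in the libraries labelled hira-1 and lower in fas2-4 were 19 against 38.7 (odds ratio 0.465), and the reverse 32 against 77.0045 (odds ratio 0.383). The genes with the strongest evidence higher in both were AT1G75945 (+8.02 and +8.04), AT3G01345 (+3.48 and +3.08), AT5G60610 (+2.56 and +2.67), AT1G07450 (+2.22 and +1.23) and AT5G35375, which had no counts in either Col-0 set (at least 25.1-fold and at least 13.8-fold). Lower in both were MAF5 (-4.80 and -2.29), AT1G04800 (-2.24 and -0.95), AT1G29720 (-1.65 and -0.95), AGL24 (-1.42 and -0.97) and ATCG00480 (-1.35 and -0.84). ATCG00480 is an organellar gene. Organellar genes together took 0.0796% to 0.252% of the counts in the libraries labelled hira-1, against 0.297% to 0.458% in their Col-0. In experiment 2 these shares overlapped between the groups. MRU1 (+3.52 and -2.41) and its neighbours AT5G35480 (+4.33 and -2.62) and AT5G35510 (+3.05 and -2.81) went opposite ways, as did AT5G52070 (+2.38 and -0.78) and HKL1 (+1.105 and -0.65). AT3G28540 (-2.20 and +1.59), TIL (-1.50 and +0.62), CRT3 (-1.15 and +0.89), IDD7 (-1.10 and +1.09) and HTR2 (-0.999 and +0.77) fell in the libraries labelled hira-1 and rose in fas2-4. Across genes, the log2 fold changes correlated weakly (Pearson 0.127, Spearman 0.0745). The excess of genes higher in both was lost without Col-0 replicate 1 of experiment 1 (2 genes, odds ratio 4.39, adjusted p = 0.135) and without fas2-4 replicate 1 (odds ratio 0.869).

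The sets of Col-0 libraries differed from each other, so neither is a stand-in for the other. Phosphate starvation genes were higher in experiment 2, with PAP17 at +3.62 (SE 0.18, adjusted p = 9.53e-06), SPX3 at +3.59, SPX1 at +3.15 and PHT1;4 at +2.67 on the log2 scale. Of 6 genes 4 were higher and 0 lower (5 up adjusted over the list alone, median +2.91, camera adjusted p = 0.000362, adjusted p = 0.417 with an estimated correlation). Clock genes were higher too, with GI at +2.28 (SE 0.23, adjusted p = 0.000201), LHY at +1.59, BOA at +2.90 and PRR5, which had no counts in experiment 1, at least 13.8-fold higher. Of 16 clock genes 9 were higher and 1 lower (11 up and 1 down adjusted over the list alone, median +0.75, also with PRR5 at its bound, camera adjusted p = 0.00199, adjusted p = 0.389 with an estimated correlation). The flowering gene CO was higher (+4.49, SE 0.37, adjusted p = 6.74e-05), and FT (-2.44), SVP (-0.84) and MAF1 (-0.48) were lower. Photosynthesis genes gave 3 higher and 15 lower of 30 (4 and 16 adjusted over the list alone, median -0.52, camera adjusted p = 0.00199, adjusted p = 0.628 with an estimated correlation), with LHCB1.2 at -1.49 and LHCA4 at -1.43. Senescence genes gave 0 and 6 of 11 (0 and 6 adjusted over the list alone, median -0.39, camera adjusted p = 0.017, adjusted p = 0.417 with an estimated correlation), with ORE1 at -3.95, SAG29 at -3.50, NAP at -3.07 and SEN1 at -1.90. S phase genes gave 9 and 0 of 22 (14 up adjusted over the list alone, median +0.56, camera adjusted p = 0.00347, adjusted p = 0.512 with an estimated correlation), and G2 and M phase 7 and 0 of 23 (7 up adjusted over the list alone, median +0.31, camera adjusted p = 0.015, adjusted p = 0.417 with an estimated correlation). DNA methylation and Polycomb gave 6 and 0 of 17 (7 up adjusted over the list alone, median +0.50, camera adjusted p = 0.0336, adjusted p = 0.646 with an estimated correlation). DNA damage gave 6 and 0 of 25 (6 up adjusted over the list alone, median +0.43, camera adjusted p = 0.0398, adjusted p = 0.628 with an estimated correlation, 0.125 with the length correction). Called members of the anthocyanin list were 9 of 14, and those of the jasmonate and ethylene list 10 of 19.

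The DNA damage list did not pass without Col-0 replicate 3 of experiment 1 (adjusted p = 0.134) or replicate 1 or 2 of experiment 2 (0.0556 and 0.0762). The DNA methylation and Polycomb list did not pass without the former (0.123) or without replicate 1 of experiment 2 (0.0556), and the senescence list not without the latter (0.135). The histone chaperone list passed without replicate 2 of experiment 1 (0.0284) or replicate 3 of experiment 2 (0.0371). Single genes higher in experiment 2 included AT2G01422 (+7.32, SE 0.28), AT4G29390 (+5.08), AT1G13609 (+4.94), PDF1.2b (+4.33), SRG3 (+4.23), AT1G47400 (+4.15) and MYB111 (+3.62). NdhL had no counts in experiment 1 and was at least 161-fold higher, but it overlaps genes on the opposite strand. Lower were AT1G80440 (-6.49, SE 0.45), AT2G29300 (-5.39), AT1G02610 (-5.05), AT1G23390 (-4.74), BT2 (-4.59), TPS8 (-4.58), AT5G62280 (-4.54), AT3G07350 (-4.52), AT2G20670 (-4.51) and TPS11 (-4.21). In all, 6498 of 19365 genes were called by edgeR, 3156 higher and 3342 lower in experiment 2, and 2420 (1286 and 1134) at least 2-fold. The libraries did not overlap for 9871 genes (51.0%), where chance gives 10%. Leaving out Col-0 replicate 1, 2 or 3 of experiment 2 gave 4074, 3593 or 3996 calls. HIRA (+0.10) and FAS2 (+0.34) were not called.

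In the tests of position of all called genes of each mutant, no chromosome, no region within 1 Mb or 2 Mb of a chromosome end and no region within 1 Mb of the targeted gene passed Fisher's exact test after adjustment, with or without a 2-fold minimum. At an unadjusted p under 0.05, chromosome 1 held more fas2-4 calls (10.6% of its genes against 9.49% elsewhere, Fisher's exact p = 0.0216, adjusted p = 0.173). With the 2-fold minimum it did so too (Fisher's exact p = 0.0466, adjusted p = 0.187), and genes within 2 Mb of a chromosome end held fewer (4.33% against 5.18%, Fisher's exact p = 0.0225, adjusted p = 0.18).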

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

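Tests chosen only after the result was seen are those of the Col-0 libraries' own length trend, of long transcripts against genotype (also within pairs), of the length correction on strongly changed genes, of distance to HIRA, of genes shared with other comparisons, of the length correction and gene-level counts for HIRA, of an exchange of all labels in experiment 1, and of the splits that part its pairs. The rule for the shared-gene test was also tightened after its value was seen.

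The results listed here stood out in the test of the difference between the effects in fas2-4 and in the libraries labelled hira-1. Mutant and experiment cannot be told apart in that test, since each mutant is in 1 experiment only. That test called 2331 genes. The named genes were AT2G18193 (5.20), AT1G68200 (5.06), AT4G22960 (4.51), SBT3.3 (4.13), GMI1 (4.12), AT3G29639 (-7.73), AT1G36675 (-6.98), AT5G35480 (-6.94), AT1G06993 (-6.91) and MRU1 (-5.93), as log2 differences, fas2-4 minus the libraries labelled hira-1. The lists were DNA damage response (median 1.69), G2 and M phase (0.53), salicylic acid and immune defence (1.48), light harvesting and photosynthesis (-0.38) and anthocyanin and flavonoid synthesis (1.89). With an estimated correlation 0 of the 25 lists passed. Of 100 drawn splits within the experiments (of 200), 2 gave as many called genes, the real one included, and the highest other split gave 2449. The numbers were taken, from the counts alone, to pair the libraries of experiment 1. The real split was therefore also set against all 80 splits that part these 3 pairs. Of these 4 gave as many genes, the real one included, which is not under 1 in 20, so the splits do not exclude chance alone. The highest other split gave 3835. All 4 kept the labels of experiment 1 and so hold any effect there, with those of experiment 2 kept, regrouped or reversed, which makes their share a weak test. Among the 80, splits that broke up the labels of experiment 1 gave at most 29. Among the 100 drawn splits, which need not part the pairs, a split of that kind gave 892. For the single comparisons, 10 splits are too few for a share under 0.05. The real splits gave 2575 (libraries labelled hira-1), 1948 (fas2-4) and 6498 (Col-0 sets) called genes, each reached by 1 split, and the highest other split gave 0 in each of them.

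The first pattern is the length trend of the libraries labelled hira-1. GC content as the whole cause is excluded, since the correlation with exon length across genes stayed at -0.509 after a GC correction. A length-dependent recovery of RNA that differs between libraries whatever their genotype is a candidate explanation, because Col-0 replicate 3 of experiment 1 shows the same trend against its own group (-0.496). An effect of the genotype on long transcripts cannot be told apart from it, since the exact permutation test of the longest of 5 equal groups of genes gave p = 0.2, where 3 against 3 libraries cannot go below 0.1. Within the 3 pairs the difference had 1 sign (-0.763, -0.512 and -0.656), but 3 pairs cannot go below p = 0.25 in an exact 2-sided sign-flip test.

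The second pattern is the set of 16 genes switched at least 16-fold (13 higher, 3 lower) in the libraries labelled hira-1. The length trend is excluded as the whole cause, since 15 of the 16 stayed called at that size after the length correction. Variants linked to HIRA are excluded as the source of most of them, since 3 of the 16 lie within 5 Mb of it. Genes whose state differs between seedling stocks whatever their genotype stay open. AT1G75945 is 1 of the 16 and also among the 30 genes in this test that switched in fas2-4 or between the Col-0 sets (Fisher's exact 1-sided p = 0.016), but a test that rests on 1 shared gene cannot decide. An effect of the genotype stays open too, and was not tested apart from these.

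The last pattern is the level of HIRA, which was not lower in the libraries labelled hira-1. A swap of some labels between the groups of experiment 1 is excluded, since the labelled split gave 16 strongly changed genes without overlap and the highest other split gave 0. That count cannot see an exchange of all labels, which is argued against because at 16 of these 16 genes the Col-0 libraries of experiment 2 lay nearer to those labelled Col-0 in experiment 1. A lower level hidden by the length trend is excluded as well, since the length-corrected log2 fold change was 1.49 (SE 0.403). Transcripts of the disrupted gene that are still counted on either side of an insertion could explain the level, but the gene-level log2 fold change of 0.56 cannot tell this from another genotype or a wrong label for all 3 libraries.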

How the results depend on the processing

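The length and GC corrections, alone or with the replicate block, and the fit without both libraries numbered 3 of experiment 1 were chosen after seeing the data. Where no reason is given, the cause was not tested.

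For the libraries labelled hira-1, the count of 2575 became 1388 with a 2-fold minimum, 4381 with DESeq2, 5999 with all 12 libraries in 1 fit and 1284 by limma on TMM-scaled TPM without a filter. It was 1545 with the length and GC correction and 1651 without both libraries numbered 3. With the replicate block it was 9593, and 7190 with block and length correction. For fas2-4, 1948 became 993 (2-fold), 2923 (DESeq2), 1117 (all 12 libraries), 3333 (length), 3373 (length and GC) and 3081 (length and block). The block alone gave 1465, and since the numbers do not pair these libraries this is no weaker effect; 1 of the 3 same-number correlations was the highest of its library. For the difference, 2331 became 4153 (DESeq2), 6461 (block) and 5872 (block and length). For the Col-0 sets, 6498 became 2420 (2-fold) and 6013 (block). RLE, upper-quartile, voom and the CPM filter moved no count by more than 1.5 times.

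Leaving out 1 library gave 19 to 5021 calls for the libraries labelled hira-1, 643 to 5661 for fas2-4, 723 to 4844 for the difference and 3593 to 7608 for the Col-0 sets. Lists passing camera ranged from 0 to 1, 9 to 11, 5 to 7 and 5 to 9 in the same order. HIRA ranged from 0.21 to 0.74 in the libraries labelled hira-1 and from -0.25 to -0.03 in fas2-4, and FAS2 from -0.86 to -0.39 and from -0.55 to -0.33. No named gene reversed. Fits with fewer libraries have less power, and the cause of the gains without fas2-4 replicate 1 or replicate 2 labelled hira-1 was not tested.

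With an estimated correlation, 0 lists passed camera in fas2-4, the difference and the Col-0 sets. By fry 13, 6 and 7 lists passed after adjustment in the same order, against 9, 5 and 8 by camera with the preset correlation. With the length correction 2 passed in the libraries labelled hira-1. The log2 fold change of HIRA in those libraries passed the threshold with the length correction (1.49) and with block and length (1.31), and FAS2 there with the block (-0.63).

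The overlap of calls was the least stable result. The odds ratio of genes lower in both passed with no filter (1.40), with the length correction (1.61) and with length and block (1.47), where that of genes higher in both did not pass (1.02). Without 1 library it ranged from 0.869 (without fas2-4 replicate 1, a reversal) to 5.75 for higher in both, from 0 to 15.99 for lower in both, from 0.457 to 16.02 for higher in the libraries labelled hira-1 and lower in fas2-4, and from 0.287 to 3.07 for the reverse. The third of these reversed without Col-0 replicate 1 or 2 of experiment 1 (16.02 and 7.15), replicate 1 labelled hira-1 (11.7) and fas2-4 replicate 1 (1.28). All but the last rest on 3 or 4 genes. The block changed no call of a set test in the mutants. The tests recovered fewer simulated 2-fold changes in experiment 1 than in experiment 2, and no run told depth from spread.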

Other observations

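The test in this part was chosen only after the genes and their positions were seen, and its count over regions was added after the count over genes.

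The genes switched on at least 16-fold in the libraries labelled hira-1 lie mostly in chromosome regions rich in pseudogenes. Of the 13 genes, 11 fall in the 10% of tested genes with most annotated pseudogenes within 500 kb (at least 30), against 10.3% of the other tested genes (Fisher's exact 1-sided p = 9.34e-10). Their median is 130 nearby pseudogenes, against 10 for the others. Neighbouring genes are not independent. Counted as regions more than 500 kb apart, 5 of 7 fall in that 10% (Fisher's exact 1-sided p = 0.000207). Only the switched-on genes were merged into regions, while the other tested genes were counted singly. That p-value therefore does not take out the dependence among neighbouring genes of the background. The background was also not matched for a low level in Col-0. The count over genes gave 2 of 25 switched-on genes in fas2-4 (p = 0.73, Fisher's exact test) and 2 of 12 between the Col-0 sets (p = 0.357, Fisher's exact test). A candidate explanation is a loss of silencing in such regions in the libraries labelled hira-1. It is a hypothesis found and tested on the same genes, and it does not separate an effect of HIRA from a difference between seedling stocks.

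Besides the genes named by rule, the switched-on genes AT2G11405 (0 counts in Col-0, 98 in the libraries labelled hira-1), AT2G10975 (+7.07), AT4G07940 (+4.86) and AT3G29638 (+4.55) belong to this set, and were picked after their values were seen.

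The 3 genes switched off in those libraries lie close together on chromosome 5. AT5G64490 (log2 -4.37, adjusted p = 0.023, edgeR), MAF4 and MAF5 (25997504 to 26002619) lie in the stretch around FAS2. AT5G64490 was picked after its values were seen, and no test of this placement was run.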
